A study of Enterobacter sp. SA187 with 12 samples.

How the data were processed

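RNA was sequenced from liquid cultures of the bacterium Enterobacter sp. SA187, in the yellow strain SA187Y and the white strain SA187W, at 6 h and at 18 h of growth. Each of the 4 groups of strain and time held 3 libraries, 12 in all, grouped by their labels alone. Per the labels, cells grew in LB at 28 °C and 220 rpm, total RNA was extracted with a RiboPure Bacteria kit, and sequencing was done at Novogene. The submitters name TopHat2 2.0.13 for alignment, featureCounts 1.5.0-p3 for counting and DESeq2, with no version, for normalization. Strandedness of counting and handling of reads with several matches are not stated.

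The deposited table holds log2 values of normalized counts, log2(normalized count + 1), for 4221 genes. This was tested on the values: after undoing the logarithm, 100% of the values in every library were whole multiples of 1 read, within 0.01, so that the reads per library could be recovered. The deposited annotation holds 4606 genes on contig.1.cir, of which 4347 are protein-coding calls, and all 4221 genes of the table matched one of these. The other 385 annotated genes, among them 22 rRNA genes and 84 tRNA genes, are not in the table, so rRNA content could not be measured. A gene symbol could be assigned to 2856 of the genes in the table. It was taken from the annotation's symbol or, where that gave none, from its product text. Genes added to a gene list by product could take the list's symbol, and lcyB is called crtY. Products are those of the annotation, and where the symbol and the product disagree the gene is named by its locus tag.

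Genes with a mean of at least 10 normalized counts over the 12 libraries were tested, 4082 in all. One limma model (limma 3.58.1 in R 4.3.3, trend on the mean) with the 4 groups as terms was fitted to log2(normalized count + 1), with 8 residual degrees of freedom. It gave the strain difference at each time, the difference between times in each strain, and the difference between the strain differences (interaction), with Benjamini-Hochberg adjusted p under 0.05 over all genes tested as the threshold. Strain differences are SA187W minus SA187Y and time differences are 18 h minus 6 h, each with the standard error (SE) of the fit. The p-values measure only the spread between libraries, since the labels do not say whether the 3 libraries of a group came from separate cultures. In a simulation on these libraries at 18 h, limma recovered 39% of genes given a 4-fold change and 7% of genes given a 2-fold change. The simulated spread was drawn independently for each gene and library. It holds no library in which many genes moved together, so these shares may not apply to the real fits.

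The comparisons, the alternatives, 25 gene lists and the rule for naming genes were fixed before the data were examined. In 24 lists, 3 or more members were in the table; the list of rRNA had 0. Members were matched by gene symbol or product, with 14 wrong matches removed and 4 members added by product, and some genes belong to more than one list. Lists were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the lists, which asks whether a list's members moved relative to the other genes. As alternatives, camera was run with an estimated correlation, and fry asked whether a list's members moved on balance in one direction. Members past the threshold were counted over all genes tested and adjusted over the list alone.

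The rule named rpoS, the 6 largest rises and the 6 largest falls of each strain comparison, and the 4 largest rises and falls of the other comparisons. These had to have a gene symbol or a product other than hypothetical or uncharacterised, and to pass the threshold. Except in the interaction, the libraries of one group also had to lie all above or all below those of the other. The rule also named up to 3 members of each list that camera called or that held 3 or more called genes, and every carotenoid gene. It was applied to the 9-library fit, since the fit of 12 libraries called no gene, and gave 108 genes.

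After the data were examined, 3 libraries were found to correlate better with the other time of their strain than with their own group. The fit was therefore repeated without them, on 9 libraries (3 of SA187Y at 6 h and 2 of each other group) with 5 residual degrees of freedom, and without the library numbered 2 of every group, on 8 libraries. These repeats were chosen after seeing the data. For the differences between times they are circular, since the libraries were left out for their position between the times. Leaving out libraries that lie apart from their own group also lowers the spread used in every comparison, the strain differences and the interaction included. The p-values of these repeats therefore lean low and their counts high. The strain difference averaged over both times was also added after seeing the data. In the simulation, with the same independent spread, the 9-library fit recovered 78% of genes given a 4-fold change and 35% of genes given a 2-fold change.

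The other alternatives were pseudocounts of 0.5 and 8, no filter and a mean of at least 50, TMM factors and quantile normalization in place of the deposited scaling, a replicate block, a fit of the compared groups only, limma's robust option, a threshold of 2-fold beside the adjusted p, and each library left out in turn. Another scaling moved the median difference of all genes by at most 0.102 on the log2 scale, in the 9-library fit at 18 h under quantile normalization. The planned edgeR and DESeq2 fits were not run, and voom in limma was run on the recovered reads, an alternative added after seeing the data. At 18 h the residuals of libraries of the same number correlated between the strains at 0.441, 0.613 and 0.523, so the numbers were taken to pair these libraries, and a fit of the 18 h groups with the number as a block was added. Libraries 1 and 3 also correlated across numbers, at 0.489 and 0.389, so the pairing is not specific to the number. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.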

Results

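Gene expression was measured by RNA sequencing in LB cultures of Enterobacter sp. SA187, an endophyte of plants. The yellow strain SA187Y is labelled wild type. The white strain SA187W is labelled a mutant of rpoS (SA187PBcda_000000191), the gene of the sigma factor that directs the general stress response of resting cells. Cultures were taken at 6 h, which the labels call logarithmic phase, and at 18 h, which they call stationary phase, with 3 libraries in each of the 4 groups. In SA187Y the reads assigned to genes came to 16318638, 13537180 and 12246987 in the libraries numbered 1, 2 and 3 at 6 h, and to 6790965, 11496723 and 7908712 at 18 h. In SA187W they came to 11468777, 4584774 and 12238652 at 6 h, and to 5606779, 11096462 and 6883557 at 18 h. Levels are given as log2(normalized count + 1).

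The libraries fell into sets that did not follow the time labels. The library labelled SA187Y 18 h number 2 and that labelled SA187W 18 h number 2 lay with the libraries labelled 6 h, and the library labelled SA187W 6 h number 2 lay with the other SA187W libraries labelled 18 h. Their mean correlation across genes with their own group minus that with the other time of their strain was -0.180, -0.0870 and -0.107, while it was above 0 in the other 9 libraries. The genes of nitrite reductase show it: nirB (SA187PBcda_000001018), the large subunit, stood at 17.03 and 17.10 in SA187W libraries 1 and 3 labelled 6 h and at 11.10 in library 2. Among the libraries labelled SA187W 18 h, nirB stood at 9.75 and 11.21 in libraries 1 and 3 and at 15.63 in library 2. The 7 libraries with 11096462 to 16318638 reads were also those with the profile of 6 h, and the 5 with 4584774 to 7908712 reads those with the profile of 18 h. Counts of single genes are therefore given with all 12 libraries and, chosen after seeing the data, with the 9 that remain without these 3. For a list, camera was run with both, and its value with 9 is given where the call was lost. The median with 9 is given where it differs by over 1.5 times.

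**Figure D1:**
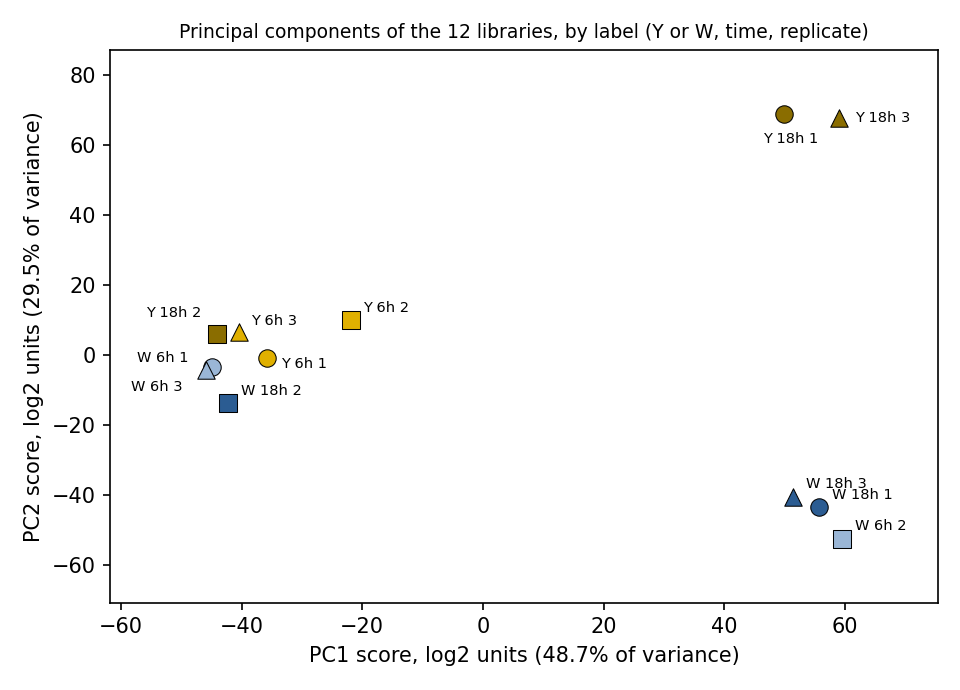
Scores of the 12 libraries on the first and second principal components of the log2 values of the 4082 tested genes, which hold 48.7% and 29.5% of the variance. Each point is a library, with color for its labelled group and shape for its replicate number, and the libraries numbered 2 of SA187Y 18 h, SA187W 18 h and SA187W 6 h lie away from the rest of their groups.

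The gene named as mutated, rpoS, at 138660 to 139652 of contig.1.cir, kept an abundant RNA in SA187W. Its level in the 3 libraries labelled SA187W was 15.06, 17.30 and 15.04 at 6 h and 16.65, 14.15 and 17.21 at 18 h. In SA187Y it was 14.87, 14.92 and 15.02 at 6 h and 15.45, 14.22 and 16.70 at 18 h. The strain difference was 0.86 ± 0.90 (SE, n = 3 per group) at 6 h, with a limma adjusted p of 0.943, and 0.55 ± 0.90 at 18 h, with an adjusted p of 0.797. With 9 libraries it was 0.11 ± 0.34 at 6 h (limma adjusted p = 0.910) and 0.86 ± 0.38 at 18 h (limma adjusted p = 0.0927). The labels do not give the kind of mutation. The 18 h value with 12 libraries changed sign, uncalled, to -0.07 without SA187Y 18 h library 2 and to -0.06 without SA187W 18 h library 3.

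**Figure D2:**
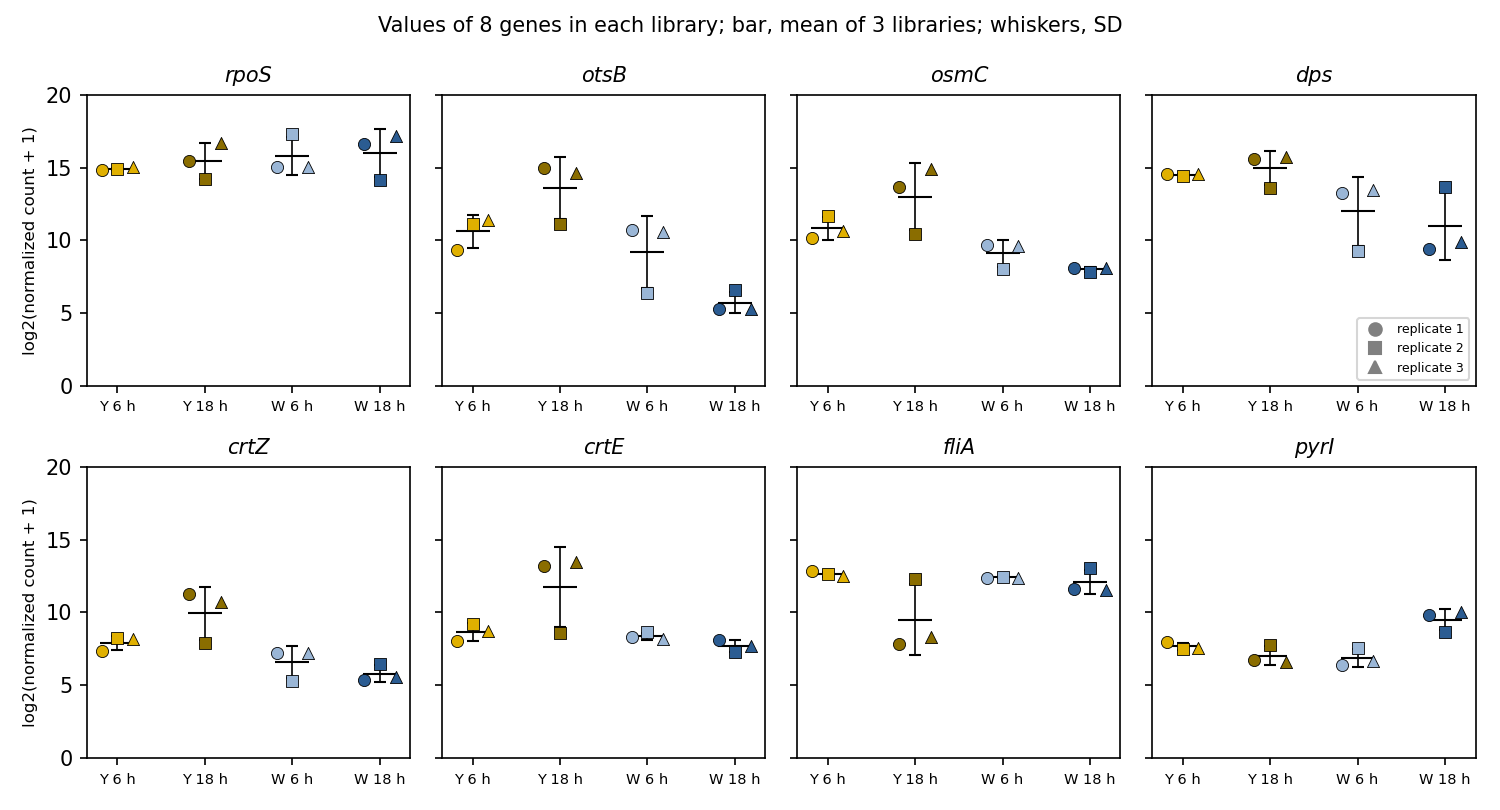
Levels, as log2(normalized count + 1), of 8 genes in each of the 12 libraries by labelled strain (Y, SA187Y and W, SA187W) and time. Each point is a library, with bars for the mean of 3 libraries and whiskers for the SD; otsB, osmC, crtZ and crtE lie lower in the 3 SA187W libraries labelled 18 h than in the 3 of SA187Y, while rpoS overlaps between the strains at 18 h.

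The comparison of the strains at 18 h asks which genes differ between them in the cultures labelled stationary phase. Genes of the general stress response were lower in SA187W. Adjusted over the list alone with all 12 libraries, 18 of 27 measured genes of the RpoS general stress list fell and 2 rose, with a list median of -2.72 (camera adjusted p = 1.74e-07; adjusted p = 0.257 with an estimated correlation; fry adjusted p = 0.0193). With the library number as a block at 18 h, camera kept the list (adjusted p = 1.25e-06; adjusted p = 0.631 with an estimated correlation), while fry did not call it (adjusted p = 0.150). Without the 3 libraries, 20 fell and 2 rose over all genes tested. In that fit 951 of all 4082 genes rose and 894 fell at 18 h, and the 9-library counts in every list stand against this share. Examples are osmC (SA187PBcda_000000190), a peroxiredoxin, at -4.99 ± 0.95 with 12 libraries and -6.17 ± 0.52 with 9, and poxB, annotated as pyruvate dehydrogenase, at -4.56 ± 0.87 and -5.86 ± 0.44 (n = 3 per group, and n = 2 with 9 libraries). The DNA-protecting ferritin gene dps stood at -4.01 ± 1.27 and -6.03 ± 0.22. SA187W library 2 labelled 18 h stood at 13.68 for dps, above the 13.64 of SA187Y library 2.

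The genes of the yellow carotenoid pigments were lower in SA187W at 18 h as well. Of the 9 measured genes of the list, 7 fell, both adjusted over the list alone with 12 libraries and over all genes with 9 (list median -3.38, camera adjusted p = 1.97e-05; adjusted p = 0.287 with an estimated correlation; fry adjusted p = 0.0193). With the block fry did not call this list either (adjusted p = 0.226). These 7 lie together from 1722932 to 1730409 of contig.1.cir. The largest difference among them was in crtZ, beta-carotene hydroxylase, at -4.15 ± 0.85 with 12 libraries and -5.54 ± 0.35 with 9. In crtE, geranylgeranyl diphosphate synthase, it was -4.04 ± 1.04 and -5.43 ± 0.36, and in crtB, phytoene synthase, -3.38 ± 0.68 and -4.17 ± 0.42. The smallest was in crtX, zeaxanthin glucosyltransferase, at -2.72 ± 0.71 and -3.67 ± 0.52. For all 7 genes the 3 libraries labelled SA187W 18 h lay below the 3 labelled SA187Y 18 h. The other 2 members, elsewhere on the chromosome, did not pass. They are annotated as a NUDIX hydrolase (SA187PBcda_000005292) and an isopentenyl-diphosphate isomerase (SA187PBcda_000000390), and stood at -0.01 ± 0.27 and 0.48 ± 0.44 with 12 libraries.

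**Figure D3:**
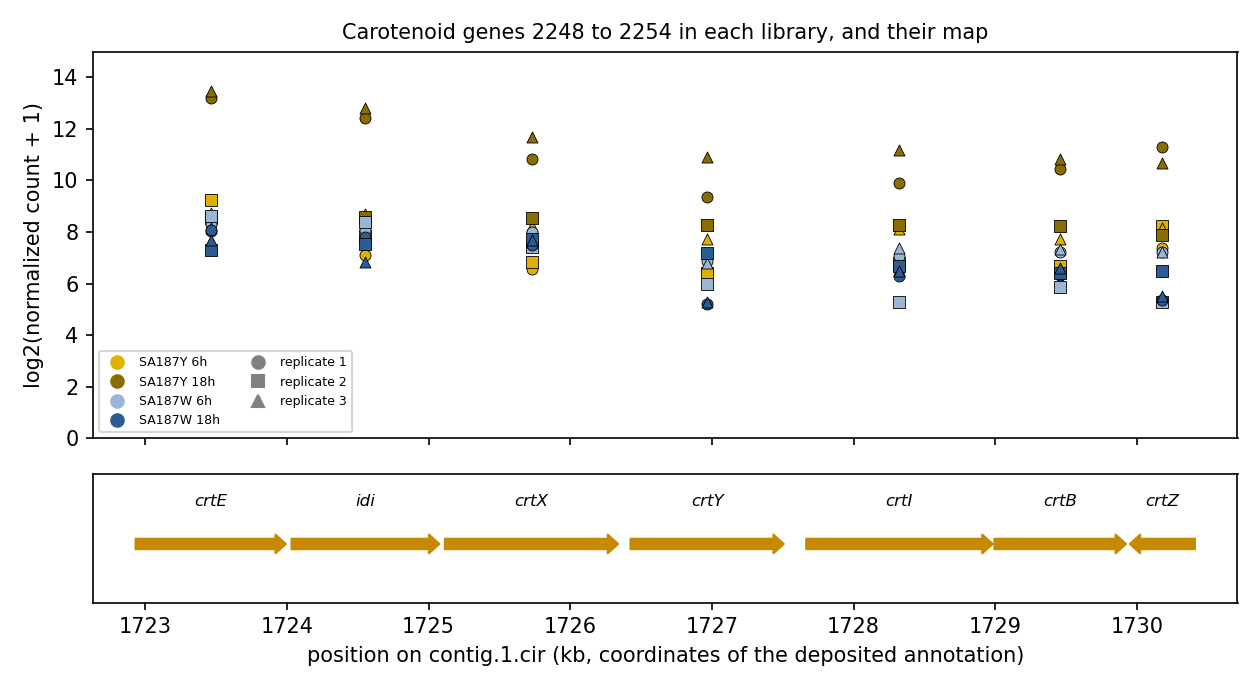
Levels, as log2(normalized count + 1), of the 7 adjacent carotenoid genes in the 12 libraries, each placed at the middle of its gene, above a map to scale with arrows for the direction of transcription. SA187Y libraries 1 and 3 labelled 18 h stand at 13.20 and 13.45 for crtE, while library 2 of the same label stands at 8.56.

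Genes of the metabolism of trehalose, a protective sugar, and glycogen, a carbon store, were lower in SA187W at 18 h. Adjusted over the list alone with 12 libraries, 11 of 17 fell (list median -2.08, camera adjusted p = 1.01e-04; adjusted p = 0.387 with an estimated correlation), and 11 fell and 2 rose over all genes with 9 libraries. The trehalose phosphate phosphatase gene otsB stood at -7.86 ± 1.27 with 12 libraries, which is 232-fold lower, and at -9.51 ± 0.58 with 9. Its neighbour otsA, trehalose phosphate synthase, stood at -4.81 ± 0.89 and -5.59 ± 0.57. The list of osmotic stress and compatible solutes shares members with the lists above, among them otsA, otsB and osmC, and is not independent of them. Of its genes 10 of 22 fell adjusted over the list alone, with a median of -1.12 (camera adjusted p = 2.57e-04; adjusted p = 0.257 with an estimated correlation). With 9 libraries 14 fell and 4 rose.

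Among the other lists that camera called lower at 18 h, 4 of 9 acid stress genes fell adjusted over the list alone, among them the lysine decarboxylase gene ldcC (SA187PBcda_000002640) at -2.61 ± 0.60 with 12 libraries (list median -0.42, camera adjusted p = 0.0195; adjusted p = 0.257 with an estimated correlation). In the list of arginine, proline and GABA catabolism 3 of 11 fell, with a median of -0.06 (camera adjusted p = 0.0256; adjusted p = 0.716 with an estimated correlation). Both list calls were lost with 9 libraries, with a camera adjusted p of 0.0772 for each, at medians of -0.45 for acid stress and -0.28 for the catabolism list. The catabolism list also lost its call with the block (camera adjusted p = 0.244). Over all genes with 9, 4 acid stress genes fell, and 5 genes of the catabolism list fell and 1 rose. The GABA breakdown genes gabD (SA187PBcda_000000825) and gabD (SA187PBcda_000002297) stood at -4.75 ± 0.93 and -3.64 ± 0.73 with 12 libraries. The RpoS general stress list as fixed also names ldcC and gabD, so the acid stress and catabolism lists are not independent of it. The capsule and exopolysaccharide list had a median of -1.21 and 0 members past the threshold adjusted over the list alone (camera adjusted p = 0.00794; adjusted p = 0.586 with an estimated correlation). With 9 libraries the median was -1.88 and 17 of its 27 members fell and 4 rose. A regulator gene of the list (SA187PBcda_000002077), whose symbol and product disagree, stood at -4.37 ± 0.39. The ribosomal protein list had a median of -0.42 over 55 genes (camera adjusted p = 0.0134; adjusted p = 0.79 with an estimated correlation). Its members past the threshold were 0 over the list alone with 12 libraries, and 19 falls and 1 rise over all genes with 9.

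Camera called the flagella and chemotaxis list higher in SA187W at 18 h, with a median of 1.44 over 87 genes (camera adjusted p = 5.96e-05; adjusted p = 0.586 with an estimated correlation). Adjusted over the list alone 2 rose and 1 fell with 12 libraries, while 50 rose and 5 fell over all genes with 9. The flagellar sigma factor gene fliA stood at 2.60 ± 0.94 with 12 libraries and 3.51 ± 0.23 with 9, and flgI (SA187PBcda_000003769), of the flagellar P ring, at 2.11 ± 0.93 and 2.82 ± 0.20. In the nucleotide biosynthesis list 2 of 22 genes rose adjusted over the list alone, with a median of 0.31 (camera adjusted p = 0.0181; adjusted p = 0.528 with an estimated correlation). This call was lost with the block (camera adjusted p = 0.0796). With 9 libraries the median was 0.64 and 8 rose and 1 fell, among the rises pyrB and pyrI, the subunits of aspartate carbamoyltransferase, at 3.15 ± 0.28 and 3.26 ± 0.26, and carA, of carbamoyl-phosphate synthase, at 3.39 ± 0.35.

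**Figure D4:**
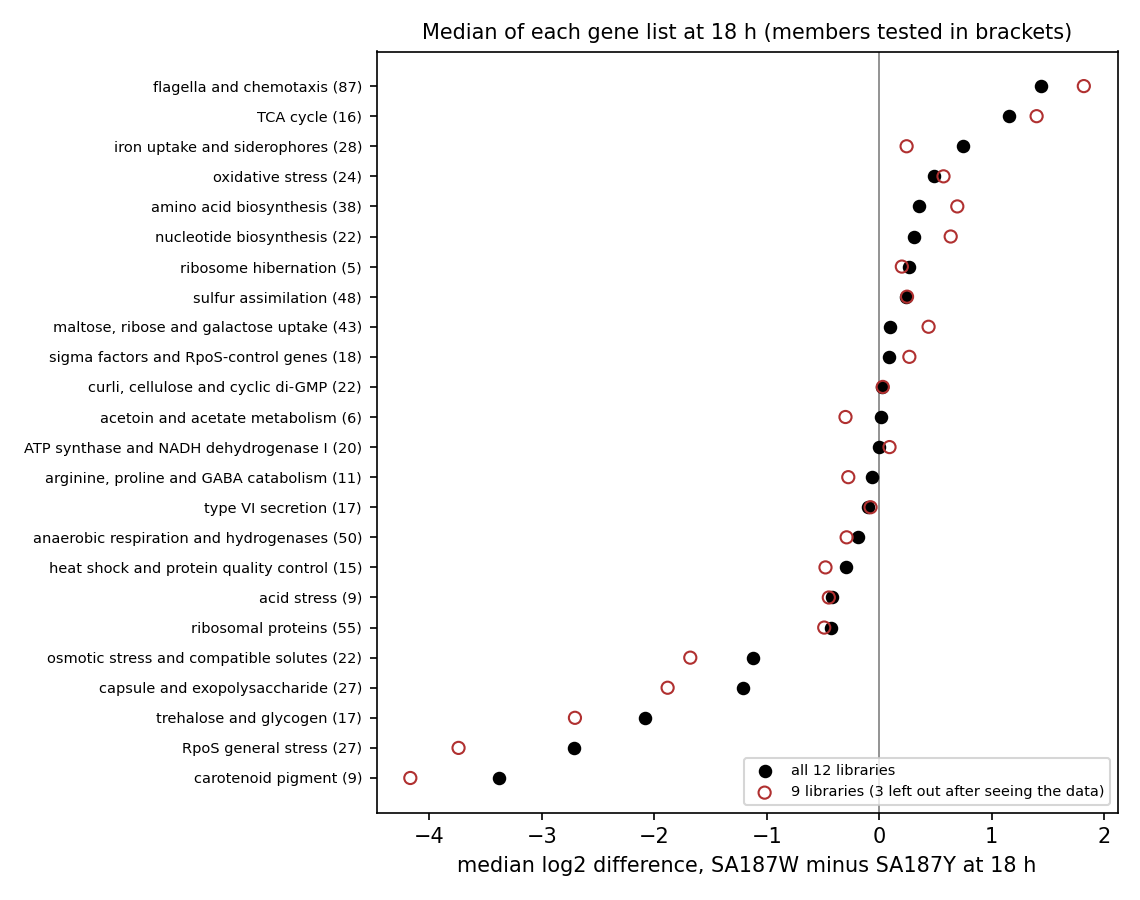
Median log2 difference, SA187W minus SA187Y at 18 h, over the tested members of each gene list with all 12 libraries (filled) and with 9 (open). Carotenoid and RpoS general stress lists lie lowest, at -3.38 and -2.72 with 12 libraries, and flagella and chemotaxis highest, at 1.44.

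Among genes with a symbol or a described product, the largest falls at 18 h with 9 libraries were in a predicted regulator (SA187PBcda_000001723) at -9.63 ± 0.53, yciE at -9.56 ± 0.86, otsB and a manganese catalase gene (SA187PBcda_000000181) at -9.06 ± 0.83. A locus annotated as a flagellar hook-length control protein (SA187PBcda_000003254) at -8.13 ± 0.61 and an oxidoreductase gene (SA187PBcda_000000344) at -8.12 ± 0.83 followed. The largest rises among such genes were in a methylase gene (SA187PBcda_000005122) at 6.80 ± 0.68, the chemoreceptor gene trg (SA187PBcda_000004330) at 4.96 ± 0.37, a ligase gene (SA187PBcda_000005123) at 4.77 ± 0.44, the ferritin gene ftnB at 4.68 ± 0.43, a protein kinase gene (SA187PBcda_000004272) at 4.52 ± 0.71 and the threonine transporter gene tdcC at 4.50 ± 0.56. With all 12 libraries limma called 0 of 4082 genes, against 808 at an unadjusted p under 0.05, and voom called 0; the smallest adjusted p was 0.0660. With the library number as a block and only the 18 h groups in the fit, limma called 3 falls, in osmY at -4.83 ± 0.27, SA187PBcda_000002342 at -4.15 ± 0.30 and an osmoprotectant transporter gene (SA187PBcda_000005139) at -4.67 ± 0.34. Without SA187Y 18 h library 2 alone, limma called 738 genes, without SA187W 18 h library 2 alone 196, without SA187W 6 h library 2 alone 37, and without all 3 it called 951 rises and 894 falls.

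The comparison at 6 h asks which genes differ between the strains in the cultures labelled logarithmic phase. Camera called the oxidative stress list lower in SA187W, with a median of -0.44 over 24 genes (camera adjusted p = 0.00729; adjusted p = 0.328 with an estimated correlation). Fry did not call it with 12 libraries (adjusted p = 0.239). In this list 0 genes passed over the list alone with 12 libraries, while 3 fell over all genes with 9. These were the glutaredoxin gene grxA at -3.14 ± 1.27 with 12 libraries and -2.80 ± 0.37 with 9, the peroxide reductase gene ahpF at -3.53 ± 1.81 and -2.26 ± 0.37, and dps at -2.53 ± 1.27 and -1.17 ± 0.20. The library labelled SA187W 18 h number 2 stood at 15.90 for ahpF, near the 3 SA187Y libraries labelled 6 h, at 15.99, 15.90 and 16.51, while the SA187W libraries 1 and 3 labelled 6 h stood at 13.77 and 13.98. The RpoS general stress list had a median of -0.61 (camera adjusted p = 0.00215; adjusted p = 0.546 with an estimated correlation), the acid stress list -0.45 (camera adjusted p = 0.0426; adjusted p = 0.355 with an estimated correlation) and type VI secretion -0.45 (camera adjusted p = 0.0419; adjusted p = 0.654 with an estimated correlation). With 9 libraries the median of the RpoS list was -0.28. The call was then lost for acid stress, with a median of -0.28 (camera adjusted p = 0.134), and for type VI secretion, with -0.09 (camera adjusted p = 0.745). In the RpoS general stress, acid stress and type VI secretion lists 0 genes passed adjusted over the list alone with 12 libraries, and with 9 libraries 1 of them, dps, of the RpoS list, fell over all genes.

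Camera called 4 lists higher in SA187W at 6 h. Sulfur assimilation had a median of 0.51 over 48 genes (camera adjusted p = 8.45e-05; adjusted p = 0.384 with an estimated correlation), and amino acid biosynthesis 0.49 over 38 (camera adjusted p = 0.00215; adjusted p = 0.355 with an estimated correlation). Uptake of maltose, ribose and galactose had 0.51 over 43 (camera adjusted p = 0.00729; adjusted p = 0.384 with an estimated correlation) and capsule and exopolysaccharide 0.42 over 27 (camera adjusted p = 0.0473; adjusted p = 0.718 with an estimated correlation). The medians with 9 libraries were 0.39 for sulfur assimilation, 0.32 for amino acid biosynthesis, 0.18 for the sugars and 0.24 for capsule. Adjusted over the list alone 0 genes passed in these lists with 12 libraries, and fry called none of them. With 9 libraries the maltose genes malF and malM rose, at 2.71 ± 0.26 and 2.24 ± 0.28, as did malQ at 1.90 ± 0.22, gntT, a gluconate transporter gene, at 2.05 ± 0.28 and a gene annotated as a major facilitator transporter (SA187PBcda_000001741) at 3.77 ± 0.39. Among genes with a symbol or a described product, the largest fall with 9 libraries was in a chemoreceptor gene (SA187PBcda_000004132) at -3.26 ± 0.35, followed by SA187PBcda_000001723 at -2.92 ± 0.49, and hemH, ferrochelatase, also fell, at -2.47 ± 0.42. The 9 carotenoid genes did not pass: crtZ stood at -1.34 ± 0.85 and crtE at -0.30 ± 1.04 with 12 libraries. With all 12 libraries limma called 0 genes at 6 h, against 100 at an unadjusted p under 0.05, voom called 0, and the smallest adjusted p was 0.943. With 9 libraries limma called 12 rises and 15 falls, which became 102 without SA187Y 6 h library 3. They became 0 without either of the SA187W 6 h libraries numbered 1 and 3, where 1 library is left in that group and is assumed to vary like the other groups.

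The strain differences at the 2 times were compared gene by gene. Across the 4082 genes, which are not independent replicates, Pearson's r between the difference at 6 h and that at 18 h was 0.456 and Spearman's rho 0.367 with 12 libraries, with 0 genes called at either time. With 9 libraries r was 0.189 and rho 0.0404, and the overlap of the called genes did not pass: 4 rises were shared where chance gives 2.80 (Fisher's exact p = 0.491), and 4 falls where chance gives 3.29 (Fisher's exact p = 0.753). Both dps and SA187PBcda_000001723 fell at both times with 9 libraries. Averaged over both times, a contrast added after seeing the data, the RpoS general stress list had a median of -1.76 with 12 libraries (camera adjusted p = 9.05e-08; adjusted p = 0.277 with an estimated correlation), with 16 of 27 falling adjusted over the list alone, and with 9 libraries 19 falling and 2 rising over all genes. The carotenoid list had -1.85 (camera adjusted p = 5.9e-04; adjusted p = 0.405 with an estimated correlation), with 6 of 9 falling, and 7 with 9 libraries. Limma called 0 single genes for this average, against 671 at an unadjusted p under 0.05, and voom called 0; without SA187Y 18 h library 2 limma called 479, without SA187W 18 h library 2 75, and with 9 libraries 1381.

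The difference between times in SA187Y compares the wild type's libraries labelled stationary phase with those labelled logarithmic phase. Library 2 labelled 18 h had the profile of 6 h. Of the flagella and chemotaxis genes 32 of 87 fell and 2 rose adjusted over the list alone with 12 libraries, with a median of -1.97 (camera adjusted p = 1.16e-07; adjusted p = 0.581 with an estimated correlation). Of the carotenoid genes 7 of 9 rose, with a median of 2.70 (camera adjusted p = 2.89e-05; adjusted p = 0.433 with an estimated correlation), and of the trehalose and glycogen genes 8 of 17 rose, with 1.91 (camera adjusted p = 3.95e-04; adjusted p = 0.581 with an estimated correlation). Ribosomal protein genes had a median of -1.03 (camera adjusted p = 3.01e-10; adjusted p = 0.598 with an estimated correlation), with 0 passing over the list alone. The RpoS general stress list had a median of 1.47 (camera adjusted p = 0.0269; adjusted p = 0.598 with an estimated correlation), with 1 gene rising and 1 falling over the list alone. Over all genes with 9 libraries 55 flagella and chemotaxis genes fell and 7 rose, 7 carotenoid genes rose, and 11 trehalose and glycogen genes rose and 1 fell. Of the ribosomal protein genes 46 then fell and 2 rose, and of the RpoS list 20 rose and 5 fell. The medians with 9 were -3.05 for flagella and chemotaxis and 2.86 for the RpoS list. With 9 libraries the largest falls among genes with a symbol or a described product were in nirD, of nitrite reductase, at -6.01 ± 0.71, ilvC, of branched-chain amino acid synthesis, at -5.99 ± 0.24, and ahpF at -5.98 ± 0.37. The largest rises among such genes were in astB, of arginine breakdown, at 5.92 ± 0.53, the fimbrial chaperone gene fimC (SA187PBcda_000004784) at 5.73 ± 0.32, its neighbour SA187PBcda_000004785 at 5.68 ± 0.34 and astD, of arginine breakdown, at 5.54 ± 0.58. With 12 libraries limma called 0 genes, against 742 at an unadjusted p under 0.05, voom called 0, and the smallest adjusted p was 0.199; without SA187Y 18 h library 2 limma called 1004, and with 9 libraries, chosen by their place between the times, 1252 rises and 1108 falls.

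The same difference was taken in SA187W, the strain labelled as the rpoS mutant, where library 2 of each time had the profile of the other time. Of the ribosomal protein genes 30 of 55 fell adjusted over the list alone with 12 libraries, with a median of -1.50 (camera adjusted p = 8.4e-34; adjusted p = 0.39 with an estimated correlation). In nucleotide biosynthesis 8 of 22 rose, with a median of 0.76 (camera adjusted p = 7.16e-07; adjusted p = 0.255 with an estimated correlation), and the TCA cycle list had a median of 1.30 with 0 passing over the list alone (camera adjusted p = 1.68e-04; adjusted p = 0.773 with an estimated correlation). The RpoS general stress list had a median of -0.66 (camera adjusted p = 0.0137; adjusted p = 0.773 with an estimated correlation) and 0 passing. Over all genes with 9 libraries 51 ribosomal protein genes fell, 14 nucleotide biosynthesis genes rose and 4 fell, all 16 TCA cycle genes rose, and of the RpoS list 13 fell and 1 rose. The medians with 9 were -2.44 for ribosomal proteins, 3.35 for the TCA cycle and -1.22 for the RpoS list. Of the carotenoid list, not called, the median was -0.36 with 12 libraries (camera adjusted p = 0.6) and -0.59 with 9. With 9 libraries the largest falls among genes with a symbol or a described product were in the nitrite reductase gene nirD at -7.20 ± 0.78, the nitrite transporter gene nirC (SA187PBcda_000001020) at -6.93 ± 0.75 and nirB at -6.59 ± 0.80, and the largest rises among them in the glyoxylate cycle genes aceB at 9.29 ± 1.41 and aceA at 9.09 ± 1.19 and the carbon starvation gene cstA (SA187PBcda_000005332) at 8.11 ± 0.64. With 12 libraries limma called 0 genes, against 247 at an unadjusted p under 0.05, voom called 0, and the smallest adjusted p was 0.525. Without SA187W 6 h library 2 limma called 19 genes, with 9 libraries, chosen in the same way, 1033 rises and 1055 falls, and without SA187W 18 h library 2 the lists called went from 8 to 4.

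Whether the strain difference itself differed between the times was tested as an interaction. The carotenoid list was lower in SA187W at 18 h than at 6 h relative to SA187Y, with a median of -3.18 and 6 of 9 genes falling adjusted over the list alone with 12 libraries (camera adjusted p = 7.14e-06; adjusted p = 0.302 with an estimated correlation). Trehalose and glycogen followed, with -1.77 and 5 of 17 (camera adjusted p = 7.14e-06; adjusted p = 0.302 with an estimated correlation), and the RpoS general stress list had -2.37 with 0 passing (camera adjusted p = 1.03e-04; adjusted p = 0.346 with an estimated correlation). Flagella and chemotaxis moved the other way, with a median of 1.56 and 0 passing (camera adjusted p = 1.86e-06; adjusted p = 0.429 with an estimated correlation). Over all genes with 9 libraries 7 carotenoid genes and 12 trehalose and glycogen genes fell, 17 of the RpoS list fell and 2 rose, and 51 flagella and chemotaxis genes rose and 3 fell. For single genes limma called 0 with 12 libraries, against 274 at an unadjusted p under 0.05, voom called 0, and the smallest adjusted p was 0.695. Without SA187Y 18 h library 2 it called 375, without SA187W 6 h library 2 it called 4, and with 9 libraries 652 rises and 719 falls, the largest fall among genes with a symbol or a described product in otsB at -9.52 ± 0.78. The count with 9 libraries was 807 without SA187W 6 h library 1 and 844 without library 3, each with 1 library left in that group.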

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

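The tests of exchanged time labels, of strain labels, of the growth state at harvest and of the choice of libraries, and every value from 9 libraries, were chosen only after the result was seen.

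The strain difference at 18 h was tested against that at 6 h, and in 12 gene lists camera called a difference with all 12 libraries, none of them with an estimated correlation (adjusted p = 0.302 to 0.72). The median of the interaction was -3.18 for carotenoid pigment, -2.37 for RpoS general stress, -1.77 for trehalose and glycogen, -1.08 for osmotic stress and compatible solutes, -1.73 for capsule and exopolysaccharide, and -1.48 for arginine, proline and GABA catabolism. It was -0.63 for heat shock and protein quality control, -0.37 for ribosomal proteins, 0.32 for type VI secretion, 0.54 for nucleotide biosynthesis, 0.73 for oxidative stress and 1.56 for flagella and chemotaxis. With 9 libraries camera did not call the interaction of 4 of these lists: arginine, proline and GABA catabolism (median -0.34, camera adjusted p = 0.33), heat shock and protein quality control (-0.58, camera adjusted p = 0.227), type VI secretion (0.05, camera adjusted p = 0.619) and oxidative stress (0.79, camera adjusted p = 0.086). The medians of 3 lists that kept the call moved by over 1.5 times, to -1.79 for osmotic stress and compatible solutes, -0.90 for ribosomal proteins and 0.90 for nucleotide biosynthesis.

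With 9 libraries 1371 single genes had an interaction in limma. Among genes with a symbol or a described product, the largest falls were in otsB at -9.52, SA187PBcda_000003254 at -8.39, fimC (SA187PBcda_000004784) at -7.62 and SA187PBcda_000004785, a spore coat U protein gene, at -6.91. The largest rises among them were in ftnB at 5.13, the regulator gene ycgZ (SA187PBcda_000004239) at 5.85, aceB at 5.92 and SA187PBcda_000005122 at 7.57. With all 12 libraries none of these 8 passed.

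The libraries numbered 2 of SA187Y 18 h, SA187W 6 h and SA187W 18 h lay nearer to the other time of their strain. Sequencing depth alone was argued against: with every library thinned to 4584774 reads, own group minus other time was still -0.0878 or lower in all 3. Wrong strain labels were argued against for SA187W 6 h library 2. It lay at 0.967 on a scale from SA187Y (0) to SA187W (1) over 1845 genes called at 18 h. SA187Y 18 h library 2 lay on the side of its label over the 27 genes called at 6 h, at 0.282. Over the 1845 genes it lay at 0.522. The values of SA187W 18 h library 2 go both ways. It lay at -0.0728 over those 27 genes, while otsB stood at 6.58 in it and yciE at 5.31, below the lowest SA187Y libraries at 9.34 and 8.72. Over the 1845 genes it lay at 0.621, with wide overlap with the 6 h libraries, so its strain stays open. There the 6 h libraries lay at 0.517 to 0.598 in SA187Y, and libraries 1 and 3 of SA187W at 0.617 and 0.641. The 27 genes placed SA187W 18 h library 2 further to the SA187Y side than SA187Y 18 h library 2. They therefore do not read strain in these libraries. The library nearest to SA187Y 18 h library 2 was SA187W 18 h library 2 (r = 0.974). The strain of SA187Y 18 h library 2 stays open too. Exchanged time labels of both SA187W libraries may account for their places, at 0.920 and 0.103 on a scale from 6 h (0) to 18 h (1). In SA187W 18 h library 2 not every gene goes with an exchange. Its otsB stood at 6.58, where SA187W libraries 1 and 3 held 5.31 and 5.27 at 18 h and 10.72 and 10.58 at 6 h. Its dps, at 13.68, was near their 13.24 and 13.48 at 6 h. SA187Y 18 h library 2, at 0.00479, has no partner in its strain. A culture harvested in another growth state would give the same places on the scale. Time labels and growth state cannot be told apart here, because no file holds cell density or another record of the cultures.

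The lower RpoS general stress list in SA187W was weighed against 3 explanations. Scaling between libraries was argued against, since the median averaged over both times was -1.74 or lower under TMM factors and quantile normalization. The choice of libraries stays open. With 1 library left out, with 9 and with 8 the camera adjusted p was 4.25e-05 or lower (adjusted p = 0.223 or higher with an estimated correlation), but fry did not call the list in 7 of these 14 fits, with 0.0833 the highest adjusted p. A different growth state of the compared cultures stays open, since in the 6 h libraries of both strains with like profiles the median was -0.284, between the bounds set for and against it. The mutation that the labels name was not tested apart from other differences that the strains may have.

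Each count of single genes was set against other splits of the same libraries, but a real count of 0 is reached by every split, so these splits say nothing about chance. For the strain comparison at 6 h all 10 of 10 splits called at least as many genes as the real split, which called 0, and the highest other was 0; at 18 h it was 10 of 10 as well, with 0 and 0. For the time comparison in SA187Y it was 10 of 10, with 0 called by the real split and 46 by the highest other, which exchanges library 2 of 18 h with library 2 of 6 h. For SA187W it was 10 of 10, with 0 and 1545, again the exchange of library 2 of 18 h with library 2 of 6 h, which points to a structure of the samples other than their time labels. With 10 splits no share under 0.05 can be reached either. For the interaction and for the strain difference averaged over both times it was 100 of 100 drawn splits each, with 0 called by the real split and 3 by the highest other.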

How the results depend on the processing

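The fits without doubted libraries, voom, the block with only the compared groups, the average over both times and every alternative of the 9-library fit were chosen only after the data were seen. With all 12 libraries the count of single genes stayed at 0 in every comparison under both pseudocounts, both filters, TMM factors, quantile normalization, limma's robust option, the 2-fold threshold, voom and the replicate block, and in the strain and time comparisons also with only the compared groups in the fit. It changed with the libraries used. With 9 libraries limma called 27 genes at 6 h, 1845 at 18 h, 2360 between times in SA187Y, 2088 in SA187W, 1371 in the interaction and 1381 averaged over both times. With 8 libraries it called 18, 1781, 2190, 2032, 1220 and 1266. Leaving out 1 library at a time gave 0 to 738 genes at 18 h, 0 to 1004 between times in SA187Y, 0 to 19 in SA187W, 0 to 375 in the interaction, 0 to 479 averaged over both times, and 0 at 6 h. Fewer libraries that lie apart from their group, and so a smaller spread, go with the higher counts.

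Camera called 8 lists at 6 h, 10 at 18 h, 10 between times in SA187Y, 8 in SA187W, 12 in the interaction and 8 averaged over both times. With an estimated inter-gene correlation it called 0 in each of these 6. Fry called 0 at 6 h, 5 at 18 h, 3 in SA187Y, 0 in SA187W, 0 in the interaction and 3 for the average. With 9 libraries camera called 11, 9, 9, 7, 10 and 10 lists in the same order, 0 of them with an estimated correlation, and fry 1, 10, 14, 12, 11 and 10. At 6 h 5 lists were called only with 9, and in 4 of them the median changed sign against 12 libraries: ribosomal proteins from -0.07 to 0.43, the TCA cycle from 0.45 to -0.81, arginine, proline and GABA catabolism from 0.80 to -0.78 and anaerobic respiration and hydrogenases from -0.12 to 0.64. Nucleotide biosynthesis, the fifth, stood at -0.25 and -0.24 (adjusted p = 0.591 or higher with an estimated correlation for these 5). With a mean of at least 50 camera called 5 lists at 6 h, and the cause was not tested. Leaving out 1 library at a time changed the count of lists by over 1.5 times only in SA187W between times, at 4 to 9.

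The correlation between the strain differences at 6 h and 18 h moved from 0.456 to 0.189 with 9 libraries and 0.126 with 8, and from 0.181 to 0.575 with 1 library left out. The 27 genes at 6 h with 9 libraries were 11 with a replicate block, 44 with only the compared groups in the fit and 63 with voom; the cause was not tested. With 1 of the 9 libraries left out they ran from 0 to 102 (a group of 2 then keeps 1 library, assumed to vary like the other groups), the interaction from 807 to 1636 and the correlation from 0.126 to 0.226. The rpoS difference, not called, ran from -0.0709 to 1.48 at 18 h and from 0.11 to 1.24 at 6 h with 1 of the 12 left out.

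Only between the strains at 18 h did the residuals of every pair of the same number correlate above 0.1. Libraries 1 and 3 also did so across numbers there, at 0.489 and 0.389. Library 2 of both 18 h groups lay apart from its group, so the numbers are not shown to pair the samples. In all 18 pairs of the same number the residuals correlated at -0.786 to 0.613, with a median of -0.208 against 0.130 in other pairs. With the replicate block the fit of all 12 libraries called 0 genes in each comparison. With the block and only the compared groups it called 3 at 18 h and 0 at 6 h and between times in each strain. At 18 h camera then called 9 lists, losing 2 and gaining the TCA cycle (camera adjusted p = 0.0027; adjusted p = 0.646 with an estimated correlation), and fry lost all 5 of its calls and gained ribosome hibernation (adjusted p = 0.0121). With the block the 9-library fit called 1730 at 18 h, 2188 between times in SA187Y, 2026 in SA187W and 1190 in the interaction. The named genes gave 1391 values under other settings with 12 libraries. Of these 1388 kept direction and side of the threshold, and 3, not called, changed sign. No named gene was called in the fit of 12 libraries, so keeping the side there means only staying uncalled. Of 1271 values with 9 libraries 1231 kept direction and side, 27 lost the call, 2 gained it and 11, not called, changed sign. With 1 of the 9 left out, 78 of 1152 values lost the call, and with all 12 libraries 117 of 128 lost it. With 1 of the 12 left out, 106 of 1536 values gained it. No called value reversed. The planned edgeR and DESeq2 alternatives were not run, although reads were recovered; voom on these reads is the only count-based fit. Depth limits small changes: in the library with 4584774 reads 1 read stood for 2.13 normalized counts, and 121 genes were at 0.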

Other observations

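The runs of neighbouring genes, the genes that separate the strains and the side test of each library were chosen only after the data were seen.

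There were 12 runs of at least 4 adjacent genes on the same strand that each differed by at least 3 on the log2 scale at 18 h with 9 libraries. The lowest run, from 122829 to 125143 of contig.1.cir, holds yciE, the manganese catalase gene and pncC, with a median of -8.75 with 9 libraries, -6.58 with 12, and -3.00 at 6 h with 9. A fimbrial run with htrE and fimC, from 3707265 to 3712511, had -7.09, -4.80 and -0.82, and a run of 7 genes that ends in manB, a gene of mannose metabolism, from 291821 to 303180, had -5.84, -4.17 and -0.47. The manganese and iron transport genes sitA to sitD had -5.74, -3.79 and -1.62. In the other direction, the chemotaxis genes cheZ to cheR had 3.38, 2.36 and -0.37. The sulfur assimilation run cysC to cysG, from 145492 to 149867, had 3.86, 2.77 and 2.64. In the runs of sitA to sitD and of htrE and fimC, SA187Y library 2 labelled 18 h lay far below the other SA187Y libraries of that label, at 7.38 against 15.58 and 15.66 for sitB and at 7.23 against 12.71 and 13.17 for fimC.

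Some lists held called genes at 18 h with 9 libraries although camera did not call the list with 12. In that fit 951 of all 4082 genes rose and 894 fell, so called members are common in any list and are not read as a result about it. The lists named here held 22, 38, 16 and 50 tested members, in the order given. In the list of curli, cellulose and cyclic di-GMP 8 rose and 5 fell, among them csgA, the main curli subunit gene, at 3.83 ± 0.39 and the diguanylate cyclase gene dgcB at -2.82 ± 0.26 (list camera adjusted p = 0.931 with 12 libraries). In amino acid biosynthesis 15 rose and 5 fell, with the arginine synthesis genes argG at 2.92 ± 0.27 and argD at 2.17 ± 0.24 (camera adjusted p = 0.0697). In the TCA cycle list 8 rose and 1 fell, with icd, isocitrate dehydrogenase, at 2.92 ± 0.34 (camera adjusted p = 0.0781). Among anaerobic respiration and hydrogenase genes 12 fell and 3 rose, with the formate dehydrogenase gene fdnI at -2.57 ± 0.32 (camera adjusted p = 0.165).

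Of the 4082 genes 78 separated the strains in all 12 libraries whatever the time. In the 6 libraries labelled SA187W 22 were higher and 56 lower. Were every split into 6 and 6 libraries equally likely for each gene, chance would give 0.216%, or 8.84 genes. The libraries fell into sets in which many genes moved together, so 78 cannot be read as an excess over this value. Each library was then left out in turn, and its side was read on the genes that parted the other 11 by at least 1 on the log2 scale. SA187W 18 h library 2 lay on its own side for 4 of 10 such genes, SA187Y 6 h library 1 for 4 of 9, SA187W 6 h library 3 for 4 of 6 and SA187Y 18 h library 2 for 5 of 7. The other 8 libraries lay on their own side for every such gene, each tested on 4 or 5 genes. A gene that parts all 12 libraries by this gap enters every set, with the left-out library on its own side by construction. Any other gene enters only where the left-out library narrows the gap. The counts therefore cannot tell whether a strain label is right.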
